A study of Homo sapiens with 6 samples.

How the data were processed

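RNA was sequenced from human cord blood CD34+ cells, a population of blood stem and progenitor cells marked by the surface protein CD34. The cells had been cultured for 4 days in an expansion medium for blood stem cells with stem cell factor, thrombopoietin and FLT3 ligand; the labels give 100 ng/mL for the cytokines. Of the 6 samples, 3 received vehicle (0.1% DMSO) and 3 received 100 nM DOPPA, and the sample titles number them 1 to 3 in each group. The titles and treatment labels placed every sample in its group. The labels do not say whether the 3 samples of a group came from separate donors or cultures, so the p-values measure only the spread between these samples, which may be technical. The labels do not expand the abbreviation DOPPA.

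The deposited table holds whole-number counts per gene for each sample, headed as raw counts per the file headers. Per the submitters' processing notes, bcl2fastq, STAR 2.5, featureCounts of Subread 1.5.1, edgeR 3.20.8 and the genome build hg38 were used; their settings, the annotation release and whether counting used the strand are not given in the sources used here. Reads from overlapping genes and from antisense partners therefore cannot be told apart, and near-identical copies such as HBA1 and HBA2, TPSAB1 and TPSB2, the HLA class II genes and ribosomal protein genes with pseudogenes may have shared or lost reads. The same table gives the authors' log2 fold change of DOPPA over vehicle and average log2 CPM, and the authors' p-value and adjusted p-value for that comparison. The authors' exon length per gene was used only for a check of length. A further 6 columns of log2 values per sample were not used. Gene symbols, identifiers and hg38 coordinates were taken from the table as the authors gave them, and gene types from GENCODE 29, which held 17120 of the identifiers entered.

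Genes on chromosome Y and the genes XIST and TSIX were left out of every step, and 17192 genes were entered. The smallest total of an entered gene over the 6 libraries was 29 counts. Totals per library lay between 21409876 and 27055018 counts, at which 3 counts, the most that a count of 0 allows, correspond to 0.111 to 0.140 CPM. Counting intervals are exact 95% intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates were compared before averaging: the chi-square per degree of freedom of their counts over genes lay between 29.8 and 207 in all 6 pairs of libraries within a group, far above sampling noise, so no library was a copy of another.

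Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter on low counts (16714 genes kept) and the group as the term; p-values were two-sided and adjusted with the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p under 0.05. Log2 fold changes are DOPPA minus vehicle, and their standard error is the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD over the 3 libraries of a group. Where all libraries of a group had 0 counts, a fold is given as a lower bound against 3 counts over the group; with 1 to 3 counts in a group, the ratio is given with its counting interval. The 24 gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares a list with all other genes. The number of members called is given after adjustment over all genes and also adjusted over the list alone.

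The lists cover markers of blood cell types that such a culture could hold, signalling, adhesion, cell cycle and metabolism. Lists for protein kinase C, AP-1 and NF-kB signalling were included because the same abbreviation has been used for a phorbol ester, which the labels do not state. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 15 genes with the largest log2 fold change in each direction among those with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between groups, without clone-type, antisense or pseudogene names (in its application, genes annotated as pseudogenes and names of microRNA hosts were left out as well, which goes beyond the wording fixed beforehand and passed over KIR3DX1, TRBVB and MIR100HG); up to 4 members per list with the smallest adjusted p, and any member needed to describe a list; and CD34, PROM1, THY1, KIT, FLT3, MPL and the protein kinase C isoforms. Genes named outside this rule, MALAT1 in the results and others in the closing section, are said to have been chosen after their values were seen.

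The shared numbers 1 to 3 were checked for pairing. Libraries with the same number deviated together from their group means, with correlations across genes of 0.38, 0.34 and 0.31 for numbers 1, 2 and 3, while libraries of the other group with another number had correlations of -0.09 or lower. The numbers thus appear to pair the libraries, on the evidence of the data and not of the labels. The fit without a block, fixed beforehand, stayed the main one, and a fit with the replicate number as a block was run beside it. Calls and p-values are from the fit without the block, which does not use the pairing, unless another fit is named. The authors' deposited log2 fold changes correlated across genes at r = 0.999999 with the fit with the block and at 0.998 with the fit without it; genes are not independent replicates.

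The other alternatives were RLE and upper-quartile scaling, no filter on low counts, a minimum of 1 CPM in 3 samples, the DESeq2 1.42.0 Wald test, the edgeR likelihood ratio test, limma-voom, robust quasi-likelihood, leaving out each library in turn, and for the lists an estimated correlation and the fry test. Leaving out both libraries numbered 1, which leaves 2 libraries per group, and leaving out the mitochondrial genes were added after seeing the data. The fits were tested on simulated data drawn from the means and library sizes of these samples. Changes were put into 200 of the genes with a mean of at least 5 CPM. No effect of the shared replicate number was put in. For DOPPA against vehicle, simulated over 16449 genes, the fit without the block recovered 33% of the genes changed 2-fold and 94% of those changed 4-fold, none with the wrong sign, and 10 of its 137 calls were unchanged genes. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used to read the table and draw the figures.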

Results

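The data comprised RNA-seq counts from 6 samples of human cord blood CD34+ cells after 4 days ex vivo, 3 with vehicle and 3 with 100 nM DOPPA. Total counts were 21409876, 27055018 and 26599038 in the vehicle libraries 1, 2 and 3 and 24410044, 26488939 and 24668524 in the DOPPA libraries 1, 2 and 3. Genes of the mitochondrial chromosome took 21.7%, 7.98% and 7.29% of the counts in vehicle and 12.0%, 6.79% and 5.80% in DOPPA, so that the library numbered 1 had the highest share in both groups. The nuclear noncoding RNA MALAT1, chosen after its values were seen, took 0.86%, 0.53% and 0.80% in vehicle and 3.05%, 1.25% and 1.58% in DOPPA. Levels are given as mean ± SD in CPM over the 3 libraries of a group, and log2 fold changes as DOPPA minus vehicle ± SE.

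The design asks which mRNAs differed between DOPPA and vehicle. DOPPA changed the expression of 4648 of 16714 genes tested (27.8%), of which 2331 were higher and 2317 lower (edgeR quasi-likelihood, adjusted p under 0.05). Of these, 1385 were at least 2-fold higher and 1710 at least 2-fold lower. The 3 vehicle and 3 DOPPA values did not overlap in 46.1% of the genes, where chance gives 10%, and the first principal component, with 68.8% of the variance, separated the groups. Leaving out DOPPA library 1, 2 or 3 left 2726, 2702 or 2532 changed genes, and leaving out both libraries numbered 1 left 1826 changed genes, 1690 of them at least 2-fold. In the authors' deposited table, 5601 of the 17192 genes entered lie under an adjusted p of 0.05, 2833 of them higher in DOPPA. Among the 16714 genes tested here the authors' calls number 5453. The fit with the replicate block, which the authors' fold changes follow, called 5433 genes and shared 5410 calls with the authors.

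**Figure D1:**
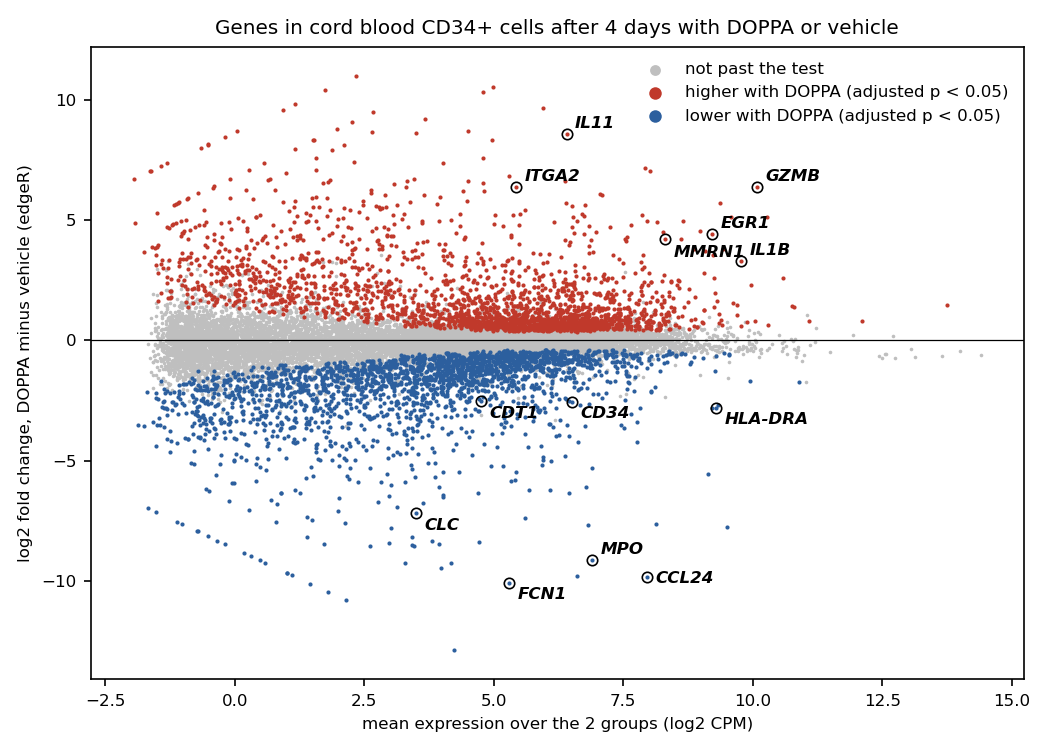
Log2 fold change (DOPPA minus vehicle, edgeR) of each of the 16714 genes tested against its mean expression over both groups in log2 CPM, with 1 point per gene. Red points are the 2331 genes called higher, blue points the 2317 called lower and grey points those that did not pass the test, and ringed genes are named in the text.

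The largest increases under the rule for named genes were in genes close to silent in vehicle. The homeobox transcription factor gene DLX3 had 0 counts in the vehicle libraries and 10.1 ± 3.52 CPM in DOPPA, at least 265-fold higher, and the phospholipase gene PLA2G4E, also at 0 in vehicle, was at least 172-fold higher. The interstitial collagenase gene MMP1 had 3 counts over the vehicle libraries and 4686 over the DOPPA libraries, a ratio of 1634 (95% counting interval 559 to 7927). MMP1 stood at 51.5, 14.9 and 124 CPM in DOPPA 1, 2 and 3, a spread that this interval does not cover. IL11, which encodes a cytokine of the IL-6 family (ENSG00000095752.6, chromosome 19, 55364389 to 55370463 on hg38), rose from 0.46 ± 0.23 to 169 ± 43.9 CPM (log2 fold change 8.59 ± 0.38, adjusted p = 5.8e-05). CYP19A1, the aromatase gene, rose from 0.052 ± 0.020 to 22.4 ± 5.54 CPM, the myoglobin gene MB from 0.18 ± 0.29 to 124 ± 50.1 CPM and the collagen gene COL5A3 from 0.23 ± 0.30 to 61.8 ± 27.6 CPM. The remaining 8 of the 15 largest increases were MALL, TAGLN3, STC1, ATP6V0A4, FAM84A, ADORA1, DNAJB8 and CHST1. DNAJB8 overlaps an antisense gene that also rose, and the counts do not part them. The noncoding gene MIR100HG and 2 genes annotated as pseudogenes, KIR3DX1 and TRBVB, were passed over in this choice although they rose more than CHST1. MIR100HG rose from 0.28 ± 0.078 to 55.0 ± 8.98 CPM, KIR3DX1 from 3 to 4151 counts, a ratio of 1448 (95% counting interval 495 to 7022), and TRBVB from 2 to 892 counts, a ratio of 467 (129 to 3859).

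The largest decreases under the same rule included genes of monocytes, macrophages and granule-forming cells. CYP27A1, the sterol 27-hydroxylase gene, fell from 37.4 ± 30.6 CPM to 0 counts in the DOPPA libraries, at least 911-fold lower, and TREM2, a receptor gene of macrophages, was at least 131-fold lower. CCL24, which encodes a chemokine for eosinophils (ENSG00000106178.6, chromosome 7, 75811665 to 75823356), fell from 497 ± 377 to 0.54 ± 0.23 CPM (log2 fold change -9.83 ± 1.10, adjusted p = 0.0012). The lipid-binding protein gene FABP4 fell from 193 ± 199 to 0.21 ± 0.26 CPM (log2 fold change -9.78 ± 1.72), and the endosomal receptor gene TLR8 fell by 8.55 on the log2 scale. The others of the 15 were OLFML2B, FCN1, TMEM176B, PDK4, STEAP4, MPO, IGLL1, RUFY4, CLEC4E and TMEM176A. The vehicle libraries differed widely in these genes: CCL24 stood at 654, 66.6 and 771 CPM in vehicle 1, 2 and 3, yet at most at 0.79 CPM in DOPPA. Limma-voom did not call FABP4, TMEM176B, PDK4, TLR8, RUFY4 and TMEM176A, with adjusted p between 0.052 and 0.25. TREM2 lost its call without vehicle library 1 or DOPPA library 2 (adjusted p = 0.054 and just above 0.05), and OLFML2B without DOPPA library 1 or 2 (adjusted p = 0.0505 and 0.054).

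Among 24 markers of primitive blood stem cells, 6 rose, 5 fell and 13 did not pass the test, so the list moved in both directions (camera adjusted p = 0.81, upward; median log2 fold change -0.03 and mean 0.11). CD34, the marker by which the cells are defined (ENSG00000174059.16, chromosome 1, 207880972 to 207911402), fell from 156 ± 76.2 to 26.7 ± 4.98 CPM (log2 fold change -2.55 ± 0.34, adjusted p = 0.0024). The stem cell transcription factor gene HLF (log2 fold change -2.32 ± 0.45), the progenitor transcript SPINK2 (-3.07 ± 0.52) and the transcription factor gene ERG (-1.58 ± 0.27) fell as well. In contrast, the laminin-receptor integrin gene ITGA6 rose from 26.0 ± 11.1 to 590.2 ± 95.2 CPM (log2 fold change 4.50 ± 0.38, adjusted p = 3.8e-04), and ITGA3, MYCT1, ESAM and HOPX also rose, by 3.46, 1.54, 1.70 and 2.36 on the log2 scale. PROM1 stood at 52.1 ± 23.5 CPM in vehicle and 34.7 ± 1.96 in DOPPA, KIT at 124 ± 37.6 and 117 ± 30.9, FLT3 at 17.1 ± 9.38 and 8.96 ± 1.08, MPL at 6.68 ± 1.79 and 7.20 ± 0.28, and THY1 at 0.27 ± 0.26 and 0.59 ± 0.51, none past the test. With p-values adjusted over the list alone, 6 members rose and 7 fell. Leaving out vehicle library 1 raised the number that fell to 8, among them PROM1 (adjusted p = 0.043), and FLT3 then had an adjusted p of 0.029.

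Genes of neutrophil granules fell as a group. Of 14 members tested, 12 fell and the other 2 did not pass the test, with a median log2 fold change of -5.33, or -5.19 with the 2 genes at 0 counts in DOPPA set to their bound (camera adjusted p = 2.6e-07; adjusted p = 0.48 with an estimated correlation). MPO, the myeloperoxidase gene (ENSG00000005381.7, chromosome 17, 58269856 to 58280935), stood at 67.1, 522 and 128 CPM in the vehicle libraries and at 0.70, 0.42 and 0.16 CPM in DOPPA (log2 fold change -9.13 ± 1.05, adjusted p = 0.0013). The neutrophil elastase gene ELANE was at least 82.2-fold lower, with 0 counts in DOPPA. In vehicle 1, 2 and 3 ELANE stood at 1.08, 6.14 and 1.80 CPM, so this bound rests mostly on library 2. CSF3R, the receptor of granulocyte colony-stimulating factor, fell from 56.1 ± 15.4 to 6.89 ± 0.37 CPM (adjusted p = 3.1e-04), MS4A3 from 19.0 ± 12.0 to 1.06 ± 0.13 CPM and S100A8 from 63.7 ± 37.3 to 2.95 ± 1.98 CPM. LYZ, the lysozyme gene, fell from 1443 ± 1914 to 6.63 ± 2.35 CPM, with 540, 147 and 3641 CPM in vehicle 1, 2 and 3, so that its vehicle mean rests mostly on library 3. When adjusted over the list alone, 13 members fell. CTSG lost its call without DOPPA library 3 (adjusted p = 0.061).

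Markers of monocytes and macrophages fell too, although the vehicle libraries held very different levels of them. Of 18 tested, 10 fell and 8 did not pass the test (median log2 fold change -2.96; camera adjusted p = 1.1e-04; adjusted p = 0.52 with an estimated correlation). The mannose receptor gene MRC1 fell from 554 ± 564 to 2.81 ± 0.44 CPM (log2 fold change -7.62 ± 1.04, adjusted p = 0.0025), the ficolin gene FCN1 from 78.4 ± 75.0 to 0.072 ± 0.092 CPM and the costimulatory ligand gene CD86 from 39.5 ± 27.5 to 0.87 ± 0.15 CPM. CD14, the lipopolysaccharide co-receptor gene, fell from 52.0 ± 41.0 to 0.15 ± 0.098 CPM, a call that limma-voom did not make (adjusted p = 0.12). CSF1R, the macrophage growth factor receptor gene, stood at 308 ± 252 and 65.6 ± 16.8 CPM and VCAN at 84.2 ± 60.1 and 116 ± 32.0 CPM, neither past the test. CSF1R passed without vehicle library 2 (adjusted p = 5.7e-04). The mean over the list of each member's level relative to its vehicle mean was 0.92, 0.20 and 1.88 in vehicle 1, 2 and 3. It was 0.20, 0.22 and 0.27 in DOPPA 1, 2 and 3, so by this mean vehicle library 2 lay within the range of the DOPPA libraries. Single members went apart: 9 lay lower in all 3 DOPPA libraries than in vehicle 2, 4 lay higher in all 3 and 5 on both sides. In the count adjusted over the list alone, 15 fell. With the replicate block 11 fell (camera adjusted p = 1.6e-05). Without vehicle library 2, 16 fell, and without DOPPA library 1, 2 or 3, 6, 5 or 6 fell; limma-voom called 4, as did the fit without both libraries numbered 1.

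Genes of antigen presentation by MHC class II fell. Of 17 members of the dendritic cell and MHC class II list, 13 fell and 4 did not pass the test (median log2 fold change -2.09; camera adjusted p = 5.4e-07; adjusted p = 0.48 with an estimated correlation). HLA-DRA (ENSG00000204287.13, chromosome 6, 32439842 to 32445046) stood at 1113, 771 and 1396 CPM in vehicle and at 156, 130.4 and 184 CPM in DOPPA (log2 fold change -2.80 ± 0.26, adjusted p = 5.7e-04). HLA-DMA, HLA-DMB and HLA-DPA1 fell by 2.54, 2.82 and 2.09 on the log2 scale, CD74, the invariant chain, from 1505 ± 216 to 460.1 ± 37.8 CPM, and CIITA, the master regulator of these genes, from 158 ± 39.5 to 37.9 ± 11.3 CPM. CD1C, a marker of conventional dendritic cells, stood at 26.2 ± 17.1 in vehicle and 63.6 ± 16.2 in DOPPA and did not pass the test (adjusted p = 0.14), but did with the replicate block (adjusted p = 0.017) and without vehicle library 2 (adjusted p = 0.040). Adjusted over the list alone, 14 fell.

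Genes of eosinophils, basophils and mast cells were split. Of 11 tested, 7 fell, 2 rose and 2 did not pass the test (camera adjusted p = 0.035; adjusted p = 0.48 with an estimated correlation), counts that were the same adjusted over the list alone. With the replicate block the list was not called (adjusted p = 0.15), nor without vehicle library 3 (adjusted p = 0.051). CLC, the Charcot-Leyden crystal protein gene of eosinophils and basophils, fell from 22.4 ± 5.14 to 0.15 ± 0.032 CPM (log2 fold change -7.19 ± 0.34, adjusted p = 6.3e-05), and the IgE receptor subunit MS4A2 and the histidine decarboxylase gene HDC fell by 2.59 and 0.96 on the log2 scale. GATA2, a transcription factor of stem cells and mast cells, rose from 439 ± 82.0 to 1216 ± 119 CPM (log2 fold change 1.47 ± 0.19), and the eosinophil granule gene PRG2 from 2.52 ± 1.36 to 14.8 ± 1.99 CPM.

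The lymphoid list was not called (camera adjusted p = 0.60), with 3 of 17 members higher, 6 lower and 8 not past the test. Its largest increase was in GZMB, the gene of the cytotoxic protease granzyme B (ENSG00000100453.12, chromosome 14, 24630954 to 24634267), which rose from 42.7, 10.7 and 23.6 CPM in vehicle to 2542, 2422 and 1444 CPM in DOPPA (log2 fold change 6.38 ± 0.59, adjusted p = 5.5e-04). The T cell receptor subunit CD3D rose from 1.38 ± 0.58 to 7.20 ± 2.67 CPM, whereas CD3E stood at 4.07 ± 3.04 and 2.77 ± 1.43 CPM and NKG7, a gene of cytotoxic lymphocytes, at 4.14 ± 0.28 and 2.76 ± 0.32 CPM, neither past the test. DNTT, the terminal transferase gene of early lymphoid progenitors, had 295 counts over the vehicle libraries and 3 over the DOPPA libraries, a ratio of 94.0 (95% counting interval 31.8 to 458), and MS4A1 fell from 588 ± 98.5 to 298 ± 32.7 CPM. With p-values adjusted over the list alone, 4 rose and 6 fell. Without DOPPA library 1, 2 or 3, 3 members fell.

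**Figure D2:**
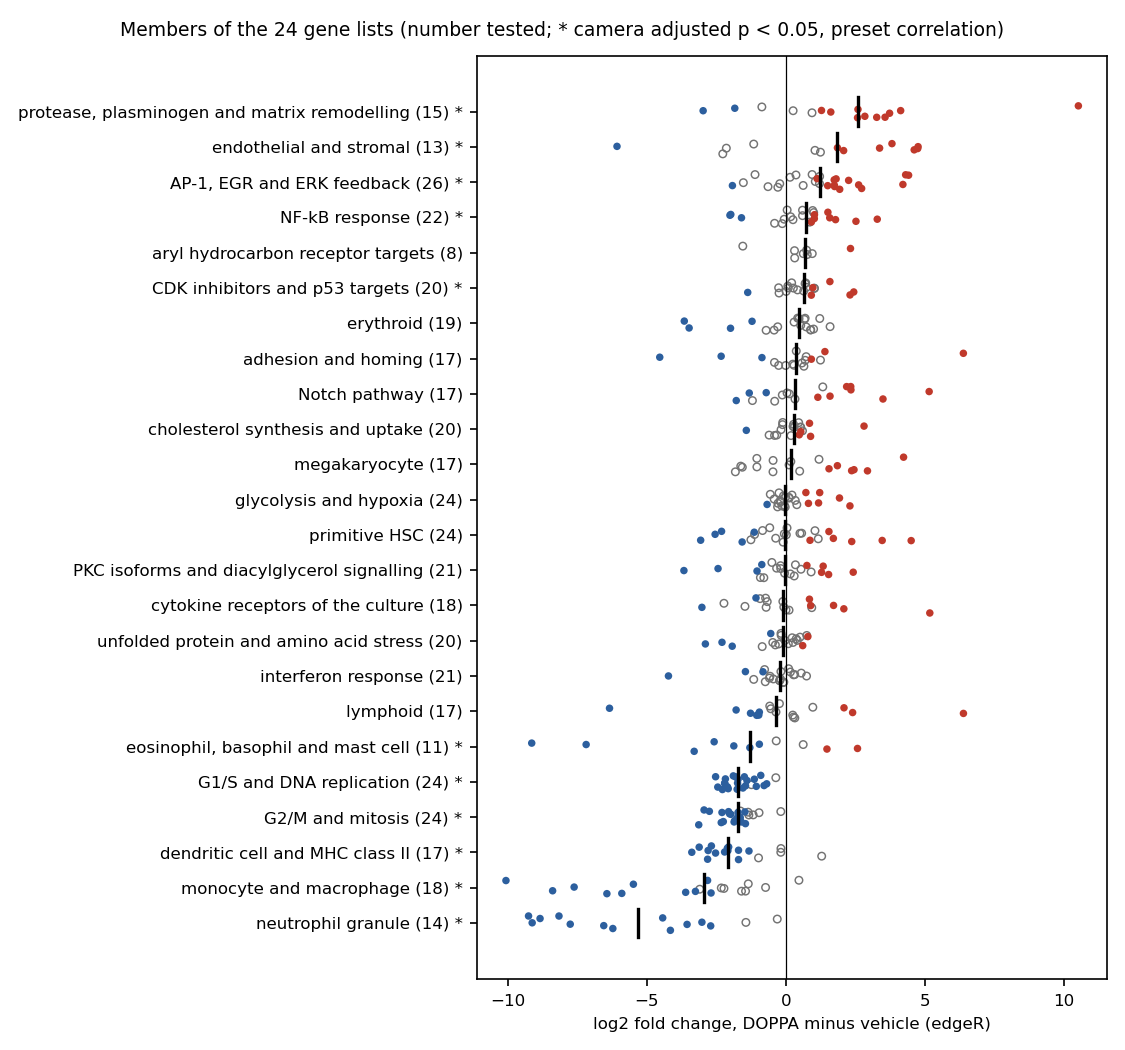
Log2 fold changes (DOPPA minus vehicle, edgeR) of the tested members of the 24 gene lists, with 1 point per gene, filled red or blue where the gene was called higher or lower and open where it was not, and a black bar at each list's median. The lists run from a median of -5.33 for neutrophil granule genes to 2.57 for proteases and matrix genes, and the 11 lists past the camera test with the preset correlation carry an asterisk.

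Megakaryocyte genes showed increases without a call of the list (camera adjusted p = 0.24). Of 17 tested, 6 rose and 11 did not pass the test; with the replicate block 6 rose and 3 fell. MMRN1, the multimerin gene of platelet granules (ENSG00000138722.9, chromosome 4, 89879532 to 89954629), rose from 32.1 ± 1.89 to 602 ± 17.0 CPM (log2 fold change 4.23 ± 0.14, adjusted p = 3.8e-05), the signalling adaptor LAT from 5.54 ± 1.03 to 28.5 ± 7.26, the von Willebrand receptor subunit GP1BA from 12.9 ± 6.13 to 98.8 ± 32.3 and the fibrinogen receptor subunit ITGB3 from 5.28 ± 3.23 to 28.7 ± 3.54 CPM. ITGA2B stood at 87.5 ± 7.67 in vehicle and 98.6 ± 9.03 in DOPPA, and the platelet chemokine genes PPBP and PF4 at 37.8 ± 24.9 and 6.29 ± 3.88 CPM in vehicle and 10.7 ± 7.38 and 2.04 ± 1.95 in DOPPA. The latter 2 were called lower with the block (adjusted p = 0.0029 and 0.0065), and PPBP also without vehicle library 3 or DOPPA library 1 (adjusted p = 0.048 and 0.040). When adjusted over the list alone, 6 rose and 1 fell. Without both libraries numbered 1, 3 rose. Without vehicle library 2, 3 fell, and without vehicle library 3 or DOPPA library 1, 1 fell.

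Of 19 erythroid genes, 4 fell and 15 did not pass the test, and the list was not called (camera adjusted p = 0.97). KLF1, the erythroid master regulator, fell from 29.5 ± 9.998 to 2.33 ± 0.35 CPM (log2 fold change -3.66 ± 0.32, adjusted p = 4.1e-04), and RHAG, BLVRB and ANK1 fell by 3.49, 2.00 and 1.22 on the log2 scale. The globin genes HBG2 and HBB lay higher in DOPPA without passing the test, HBG2 at 65.3 ± 18.6 and 130 ± 44.9 CPM and HBB at 118 ± 36.2 and 352 ± 309 CPM. HBB stood at 708, 142 and 207 CPM in DOPPA 1, 2 and 3, so its DOPPA mean rests mostly on library 1. The list's median log2 fold change was 0.47 and its mean -0.13, and the test pointed downward, but upward with the block. With the replicate block 5 members rose, among them HBB (adjusted p = 0.029), and 4 fell. A single member rose without vehicle library 2 or DOPPA library 2, and HBG2 passed without the latter (adjusted p = 0.031). ANK1 lost its call without vehicle library 1 or DOPPA library 1, 2 or 3 (adjusted p = 0.073, 0.052, 0.074 and 0.084). In the count adjusted over the list alone, 4 fell.

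The endothelial and stromal list was higher in DOPPA, with 7 of 13 members up, 1 down and 5 not past the test (camera adjusted p = 0.018; adjusted p = 0.48 with an estimated correlation). COL6A3, a chain of type VI collagen, rose from 8.28 ± 6.79 to 220.1 ± 33.5 CPM (log2 fold change 4.75 ± 0.58, adjusted p = 0.0017), the platelet-derived growth factor receptor gene PDGFRB from 2.68 ± 2.02 to 69.7 ± 17.3 CPM, COL1A2 from 0.91 ± 0.12 to 12.9 ± 4.59 CPM and the ectonucleotidase gene NT5E from 5.47 ± 4.79 to 55.5 ± 14.4 CPM. FN1, the fibronectin gene, fell from 30.4 ± 26.0 to 0.44 ± 0.17 CPM (adjusted p = 0.019). It stood at 43.3, 0.49 and 47.5 CPM in vehicle 1, 2 and 3. Vehicle library 2 thus lay within the DOPPA range, as it did in the mean over the monocyte markers. COL1A1, the partner chain of COL1A2, stood at 4.02 ± 3.85 and 0.90 ± 0.49 CPM without passing the test, except with the block (adjusted p = 0.0091) or without vehicle library 2 (adjusted p = 0.033). FN1 was not called without DOPPA library 1, 2 or 3 (adjusted p = 0.072, 0.069 and 0.073) or by limma-voom (adjusted p = 0.36). With the block 8 rose and 2 fell, and without vehicle library 2, 3 fell; adjusted over the list alone, 8 rose and 3 fell.

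Early-response genes downstream of the ERK kinases were higher. In the AP-1, EGR and ERK feedback list, 13 of 26 members rose, 1 fell and 12 did not pass the test (median log2 fold change 1.21; camera adjusted p = 8.9e-06; adjusted p = 0.48 with an estimated correlation). The zinc-finger transcription factor gene EGR1 (ENSG00000120738.7, chromosome 5, 138465490 to 138469315) rose from 53.4 ± 9.46 to 1134 ± 61.5 CPM (log2 fold change 4.41 ± 0.19, adjusted p = 5.8e-05). The ERK pathway inhibitors SPRY2 and SPRY4 rose by 4.20 and 4.30 on the log2 scale and the phosphatase gene DUSP5 by 2.61. FOS and JUN, the canonical AP-1 subunits, stood at 80.4 ± 45.0 and 87.1 ± 54.1 CPM in vehicle and 37.1 ± 4.48 and 30.0 ± 4.45 in DOPPA, neither past the test. JUN was called lower with the replicate block (adjusted p = 0.028), and both were without vehicle library 2 (adjusted p = 5.0e-04 for FOS and 6.8e-04 for JUN), where 3 members fell. DUSP1 fell by 1.93 on the log2 scale, a call lost without vehicle library 1 or 3 or DOPPA library 1 or 2 and under limma-voom (adjusted p between 0.064 and 0.096). With the block 17 members rose and 2 fell, and adjusted over the list alone 15 rose and 2 fell.

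NF-kB target genes moved in both directions with more increases than decreases. Of 22, 8 rose, 3 fell and 11 did not pass the test (camera adjusted p = 0.018; adjusted p = 0.62 with an estimated correlation), and the list was not called without vehicle library 2 (adjusted p = 0.14). The interleukin-1 beta gene IL1B rose from 163 ± 46.6 to 1585 ± 702 CPM (log2 fold change 3.28 ± 0.37, adjusted p = 0.0012), TRAF1 from 112 ± 28.9 to 643 ± 99.0 CPM, the inhibitor of apoptosis BIRC3 from 155 ± 15.4 to 441 ± 29.9 CPM, and NFKB2 from 119 ± 12.3 to 223 ± 19.1 CPM. SOD2, the mitochondrial superoxide dismutase gene, fell from 304 ± 186 to 75.1 ± 6.62 CPM, and TNFAIP2 and the chemokine gene CCL4 were the other members that fell. NFKBIA, the feedback inhibitor of the pathway, stood at 226 ± 71.0 and 269 ± 26.5 CPM and did not pass the test, except without vehicle library 3 (adjusted p = 0.041). Adjusted over the list alone, 9 rose and 3 fell. Without DOPPA library 2 or 3, 1 member fell: CCL4 had an adjusted p of 0.058 or 0.053, and TNFAIP2 of 0.072 or 0.055, and of 0.072 without DOPPA library 1.

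The list of protein kinase C isoforms and diacylglycerol signalling was not called (camera adjusted p = 0.81), with 5 of 21 members higher, 4 lower and 12 not past the test. The test pointed upward and the median log2 fold change was -0.05. The counts were the same adjusted over the list alone. RASGRP3, a diacylglycerol-binding exchange factor for RAS, rose from 42.1 ± 2.22 to 225 ± 28.2 CPM (log2 fold change 2.42 ± 0.15, adjusted p = 1.2e-04), and the protein kinase D genes PRKD2 and PRKD3 rose by 1.28 and 1.34 on the log2 scale. RASGRP4 fell from 10.5 ± 3.97 to 0.81 ± 0.22 CPM, and MARCKS, a protein kinase C substrate, from 142 ± 83.9 to 26.1 ± 6.37 CPM. Of the kinase isoforms, PRKCI rose from 36.1 ± 5.75 to 60.7 ± 1.59 CPM (adjusted p = 0.0099), with an adjusted p of 0.053 without DOPPA library 3. PRKCA, PRKCB, PRKCD, PRKCE, PRKCH, PRKCQ and PRKCZ did not pass the test, with log2 fold changes between -0.80 and 0.34. PRKCD passed as lower without vehicle library 2 (adjusted p = 0.0070). It stood at 120, 55.5 and 157 CPM in vehicle 1, 2 and 3 and at 81.5, 78.0 and 73.8 CPM in DOPPA. The library left out thus lay below all 3 DOPPA libraries.

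Proteases and matrix genes were among the strongest increases. Of 15 tested, 10 rose, 2 fell and 3 did not pass the test (median log2 fold change 2.57; camera adjusted p = 0.0023; adjusted p = 0.48 with an estimated correlation). TIMP1, a metalloproteinase inhibitor, rose from 93.3 ± 37.2 to 1102 ± 256 CPM (log2 fold change 3.56 ± 0.34, adjusted p = 6.5e-04), the sheddase gene ADAM8 from 43.5 ± 9.55 to 417 ± 45.8 CPM, the gelatinase gene MMP2 from 20.3 ± 8.27 to 145 ± 12.6 CPM and the membrane metalloproteinase gene MMP14 from 76.0 ± 61.9 to 1004 ± 56.7 CPM. TIMP2 fell from 104 ± 60.9 to 13.2 ± 3.78 CPM. With p-values adjusted over the list alone, 10 rose and 3 fell. Without vehicle library 1 or DOPPA library 2 or 3, 6 members rose, and without vehicle library 1 or 3 or any 1 of the DOPPA libraries, 1 fell.

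In the adhesion and homing list, 3 of 17 members rose, 3 fell and 11 did not pass the test, and the list was not called (camera adjusted p = 0.24). The collagen-receptor integrin gene ITGA2 rose from 1.05 ± 0.36 to 85.4 ± 11.4 CPM (log2 fold change 6.38 ± 0.27, adjusted p = 5.8e-05). SELPLG, the P-selectin ligand, fell from 35.4 ± 8.37 to 1.51 ± 0.30 CPM (log2 fold change -4.54 ± 0.27), and the L-selectin gene SELL fell by 2.33 on the log2 scale. CXCR4, the receptor by which stem cells home to the marrow, rose from 86.3 ± 24.3 to 162 ± 9.41 CPM (adjusted p = 0.015), with an adjusted p of 0.061 without DOPPA library 2. With the block 5 rose, and adjusted over the list alone 5 rose and 3 fell. The number that rose was 6 without vehicle library 3 and 1 without DOPPA library 2.

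Genes of the cell cycle were lower in DOPPA. Of 24 genes of the G1/S transition and DNA replication, 22 fell and 2 did not pass the test (median log2 fold change -1.73; camera adjusted p = 4.6e-09; adjusted p = 0.52 with an estimated correlation), and of 24 genes of G2/M and mitosis, 18 fell and 6 did not pass (median -1.74; camera adjusted p = 2.6e-07; adjusted p = 0.52 with an estimated correlation). The replication licensing factor CDT1 fell from 45.8 ± 14.6 to 7.89 ± 2.04 CPM (log2 fold change -2.53 ± 0.30, adjusted p = 0.0015), the S phase transcription factor gene E2F1 from 52.5 ± 14.1 to 11.4 ± 4.03 CPM and the helicase subunit MCM4 from 302 ± 98.9 to 89.2 ± 18.8 CPM. BIRC5 fell from 45.5 ± 19.7 to 5.88 ± 2.85 CPM and the mitotic kinase AURKB from 29.1 ± 14.1 to 4.30 ± 2.20 CPM. MKI67, the proliferation marker, stood at 142 ± 70.0 and 55.0 ± 31.0 CPM and did not pass the test, except with the block (adjusted p = 0.017) or without vehicle library 3 (adjusted p = 0.049). Adjusted over each list alone, 23 and 23 members fell. Without both libraries numbered 1, 5 G1/S and 3 G2/M genes passed the test, and without DOPPA library 1 or 3, 8 or 7 G2/M genes did; both lists were still called in each of these fits.

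The CDK inhibitors and p53 targets were higher as a list, with 5 of 20 up, 1 down and 14 not past the test (camera adjusted p = 0.018; adjusted p = 0.52 with an estimated correlation). The antiproliferative gene BTG2 rose from 336 ± 176 to 1656 ± 121 CPM (log2 fold change 2.30 ± 0.39, adjusted p = 0.0054) and GADD45A from 12.0 ± 1.26 to 35.8 ± 7.01 CPM. CDKN1A, the gene of the CDK inhibitor p21, rose from 81.7 ± 53.5 to 442 ± 58.8 CPM (adjusted p = 0.019), with an adjusted p of 0.053 or 0.057 without DOPPA library 1 or 3. CDKN2C fell by 1.38 on the log2 scale, a call also lost without those libraries (adjusted p = 0.058 and 0.055). MDM2, a p53 target, stood at 102 ± 18.9 and 102 ± 10.1 CPM. When adjusted over the list alone, 6 rose and 1 fell. Without DOPPA library 1 or 3, or without both libraries numbered 1, 2 members rose.

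**Figure D3:**
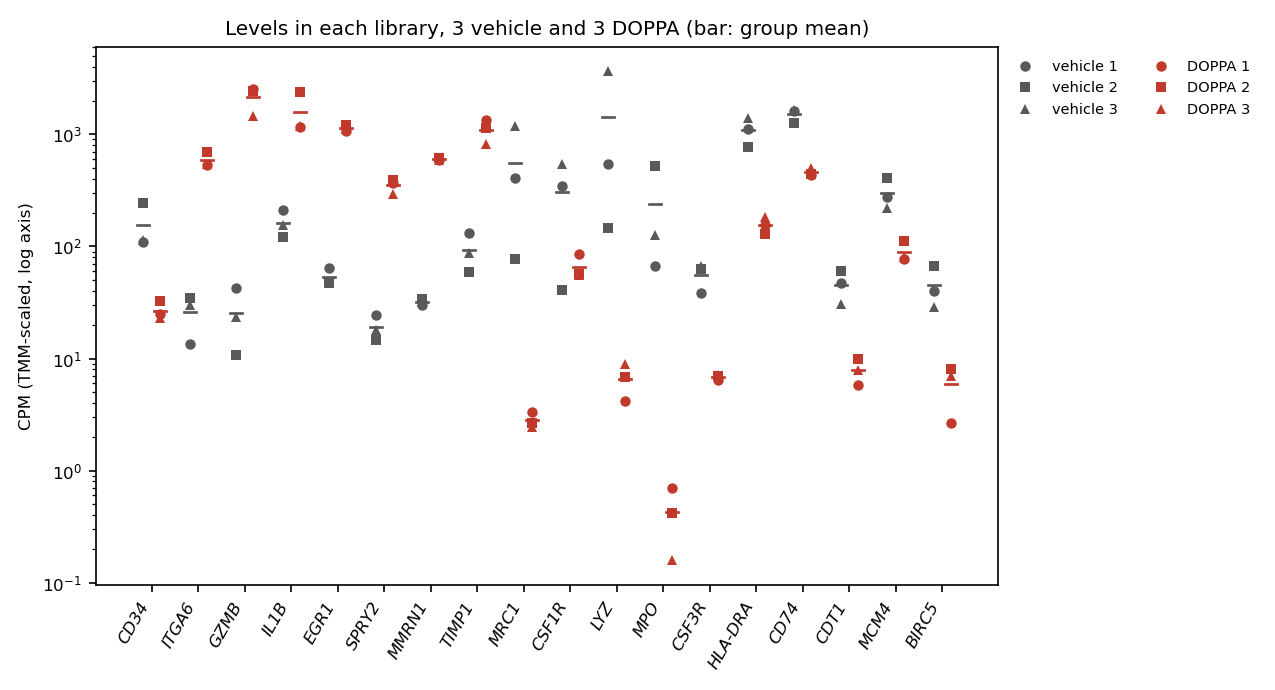
TMM-scaled CPM on a log axis of 18 genes of the text in each of the 3 vehicle (grey) and 3 DOPPA (red) libraries, with marker shape giving the replicate number and a bar at the group mean. CSF1R in vehicle library 2 lies below the DOPPA libraries, while HLA-DRA and CD74 lie higher in each vehicle library than in any DOPPA library.

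Metabolic and stress lists were not called. Of 20 cholesterol genes 5 rose, 1 fell and 14 did not pass the test (camera adjusted p = 0.16), of 24 glycolysis and hypoxia genes 6 rose, 1 fell and 17 did not (camera adjusted p = 0.40). Of 20 unfolded protein and amino acid stress genes 2 rose, 4 fell and 14 did not (camera adjusted p = 0.58), and of 21 interferon genes 3 fell and 18 did not pass (camera adjusted p = 0.24). The glycolysis list had a median log2 fold change of -0.02 and a mean of 0.25, and its test pointed upward. The sterol carrier gene STARD4 rose from 52.8 ± 14.5 to 369 ± 74.0 CPM, the glucose transporter gene SLC2A3 from 125 ± 53.5 to 614 ± 71.2 CPM and VEGFA, the endothelial growth factor gene, from 52.3 ± 10.9 to 198 ± 46.6 CPM. PHGDH and PSAT1, enzymes of serine synthesis, fell from 101 ± 34.9 to 13.6 ± 1.75 CPM (log2 fold change -2.90 ± 0.26, adjusted p = 4.9e-04) and by 2.30 on the log2 scale, and the interferon-induced chemokine gene CXCL10 fell from 4.36 ± 3.00 to 0.23 ± 0.036 CPM. Adjusted over each list alone, 7 cholesterol genes rose and 2 fell, 6 glycolysis genes rose and 1 fell, 2 stress genes rose and 4 fell, and 2 interferon genes fell. With the block, 2 cholesterol genes fell and 2 interferon genes rose. Without DOPPA library 1, 2 or 3, 2 cholesterol genes rose, and without vehicle library 3, 3 fell; upper-quartile scaling gave 3 that rose. Without DOPPA library 3, 3 glycolysis genes rose, without vehicle library 3, 3 fell and without vehicle library 1 or any 1 DOPPA library none did. At most 1 stress gene rose without any single library. Without vehicle library 1 or 3, 1 interferon gene rose.

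Of 8 aryl hydrocarbon receptor targets, 7 did not pass the test and 1 rose, CYP1A1, the receptor's most inducible gene, from 14.9 ± 4.56 to 73.6 ± 3.77 CPM (log2 fold change 2.30 ± 0.23, adjusted p = 7.0e-04), and the list was not called (camera adjusted p = 0.088). With the replicate block 3 rose and the list was called (adjusted p = 0.046), as it was without vehicle library 3 (adjusted p = 0.013). With an estimated correlation, and without the block, this list had a camera adjusted p of 0.52. CYP1B1, another target, stood at 1095 ± 762 and 373 ± 138 CPM without passing the test, except without vehicle library 2 (adjusted p = 0.0033). That library, at 262 CPM, lay below all 3 DOPPA libraries, which stood at 532, 289 and 298 CPM. Without vehicle library 1 or 3, 2 targets rose. In the Notch pathway list 7 of 17 rose, 3 fell and 7 did not pass the test (camera adjusted p = 0.087, and 0.48 with an estimated correlation). The Notch list was called without DOPPA library 2 (camera adjusted p = 0.038). The Notch ligand gene JAG1 rose from 5.08 ± 1.65 to 180.1 ± 114 CPM (log2 fold change 5.15 ± 0.52), GATA3 from 5.51 ± 1.33 to 27.7 ± 4.47 CPM, HES1, a Notch target, from 5.40 ± 0.39 to 16.2 ± 0.72 CPM and HES4 from 0.34 ± 0.17 to 1.78 ± 0.19 CPM. Adjusted over each list alone, 1 receptor target rose, and 8 Notch genes rose and 3 fell. The number of Notch genes that fell was 5 without vehicle library 2 and 1 without DOPPA library 1, and without DOPPA library 2 none of the 3 passed.

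Receptors of cytokines and their feedback genes were not called as a list (camera adjusted p = 0.87), with 5 of 18 higher, 2 lower and 11 not past the test. The median log2 fold change was -0.10 and the mean 0.04, and the test pointed upward. IL2RA, the alpha chain of the interleukin-2 receptor, rose from 5.84 ± 2.35 to 209 ± 78.4 CPM (log2 fold change 5.17 ± 0.40, adjusted p = 3.1e-04), and IL2RG, its common gamma chain, from 331 ± 36.7 to 612 ± 16.5 CPM. CSF2RB, the common beta chain of the receptors for interleukin-3 and granulocyte-macrophage colony-stimulating factor, fell from 219 ± 16.0 to 103 ± 18.4 CPM. In the count adjusted over the list alone, 5 rose and 4 fell. The number that fell was 4 without vehicle library 1 or 2, and the number that rose was 3 without DOPPA library 2.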

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

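Leaving out both libraries numbered 1 and leaving out the mitochondrial genes were chosen after seeing the data. The count of changed genes, 4648, lay between 4346 and 5593 under other scalings, filters and tests, with 5433 under the replicate block. With single libraries left out it lay between 2532 and 4605, and without both libraries numbered 1 it was 1826; these fits have fewer samples. The count of genes changed at least 2-fold, 3095, lay between 2165 and 3047 with single libraries left out and was 1690 without both libraries numbered 1. Of the 4648 genes, 4549 were also called with the block. Upper-quartile scaling moved the median log2 fold change of all genes from -0.02 to -0.13 and gave 1889 higher and 2732 lower genes in place of 2331 and 2317. Of 24 lists, 11 were called. With an estimated correlation camera called 0 of them, 2 having an unadjusted p under 0.05, and the cause was not tested; fry called 11, of which 8 were among those of camera and the others were the megakaryocyte, stress and Notch lists. The monocyte, NF-kB and G2/M lists had an adjusted p of 0.053 with fry. With single libraries left out, 10 to 12 lists were called. No called gene named in the report changed direction in any fit. The fits on simulated data recovered few 2-fold changes, so a gene that did not pass may have changed by that much: 2-fold changes were recovered in 33% of cases without the block and 16% with it.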

Other observations

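The gene families below and the genes named from them were chosen after their values were seen. Their camera p-values, adjusted only over these 7 families, therefore describe the families and cannot support them. Genes of secreted and membrane-bound cytokines changed in both directions, with more increases than decreases. Of 16 interleukin genes tested, 6 rose and 1 fell (none fell with the replicate block; camera adjusted p = 0.0054 over 7 families; adjusted p = 0.19 with an estimated correlation). Besides IL11 and IL1B, IL1A rose from 6.67 ± 3.07 to 175 ± 122 CPM (SD, 3 libraries per group), IL13 from 0.42 ± 0.17 to 16.1 ± 7.09 CPM and IL16 from 82.3 ± 18.2 to 439 ± 17.7 CPM. IL33 had 3 counts over the vehicle libraries and 442 over the DOPPA libraries, a ratio of 154 (95% counting interval 52.4 to 750.3). Of 11 genes of TNF superfamily ligands, 6 rose and 2 fell (camera adjusted p = 0.024; adjusted p = 0.24 with an estimated correlation): TNFSF4, the OX40 ligand, rose from 11.2 ± 2.67 to 293 ± 49.1 CPM (log2 fold change 4.71 ± 0.25, adjusted p = 9.2e-05), TNFSF8 from 9.42 ± 2.48 to 205 ± 84.7 CPM and TNFSF15 from 2.22 ± 0.59 to 62.2 ± 27.6 CPM, whereas TNFSF13B fell from 11.8 ± 6.60 to 2.20 ± 0.77 CPM. Of 5 genes of EGF-family ligands, 3 rose (camera adjusted p = 0.024; adjusted p = 0.26 with an estimated correlation), led by AREG, the amphiregulin gene, from 1.66 ± 0.82 to 165 ± 43.3 CPM. The other 2 that rose were EREG and HBEGF; EREG lost its call without DOPPA library 1 or 2 (adjusted p = 0.058 and 0.051).

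Collagen genes changed in both directions, with 11 of 23 higher and 6 lower (camera adjusted p = 0.044; adjusted p = 0.24 with an estimated correlation). Of the type VI collagen chains, COL6A1 rose from 62.5 ± 21.9 to 873 ± 72.5 CPM and COL6A2 from 93.1 ± 52.2 to 1283 ± 305 CPM, beside COL6A3, and COL5A1 fell from 31.5 ± 16.5 to 4.73 ± 2.52 CPM. Of 9 Toll-like receptor genes 5 fell (camera adjusted p = 0.071), TLR4 from 53.1 ± 44.6 to 2.66 ± 0.99 CPM (limma-voom adjusted p = 0.060) and TLR2 from 90.6 ± 74.4 to 6.04 ± 3.83 CPM. In vehicle 1, 2 and 3, TLR4 stood at 50.02, 10.2 and 99.2 CPM and TLR2 at 76.3, 24.4 and 171 CPM, in the same order as the monocyte and macrophage markers. TLR6 stood at 30.0 ± 12.5 and 62.8 ± 16.6 CPM and did not pass the test (adjusted p = 0.057), but was called higher with the block (adjusted p = 0.0063) and by limma-voom (adjusted p = 0.046), DESeq2 (adjusted p = 0.014) and the likelihood ratio test (adjusted p = 0.017). Of 77 genes of cytosolic ribosomal proteins, 16 fell and the others did not pass the test (median log2 fold change -0.40; camera adjusted p = 1.1e-07; adjusted p = 0.42 with an estimated correlation), and the median was -0.41 and -0.52 with RLE and upper-quartile scaling. The directions of the medians of the other families were also kept under both scalings. None of the 13 mitochondrially encoded mRNAs was called (edgeR; 0 at an unadjusted p under 0.05; median log2 fold change -0.58; camera adjusted p = 0.18), while the block called 1 of them and gave the family a camera adjusted p of 0.017. With an estimated correlation, and without the block, the family had an adjusted p of 0.71.

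Of the tests below, those on mitochondrial shares, on single vehicle libraries, on monocyte-like cells, on stromal cells and on the libraries numbered 1 were chosen only after the results were seen. The cell cycle genes fell in DOPPA. Under scaling to total counts, a larger share taken by mitochondrial transcripts would lower all other genes alike. The share left to them was not smaller in DOPPA, with a mean log2 ratio to vehicle of 0.070 ± 0.085 (SD, 3 pairs). This followed from the mitochondrial percentages given above. TMM scaling, and a comparison of a list with other genes, are little affected by such a shift, so the result adds no support to the fall. The fit without the mitochondrial genes hardly moved any value and decides nothing here. A trend with gene length does not account for the fall, as the median log2 fold change of the 48 genes was -1.67 ± 0.11 after its removal (SE of the median over genes, here and below). This SE treats the genes of a list as independent and leaves out the spread between libraries. Without both libraries numbered 1, with 2 libraries per group, the median was -1.65 ± 0.11, although fewer single genes then passed. What stays open is whether the cultures held fewer dividing cells or whether dividing cells carried fewer of these transcripts, and a biological effect of DOPPA is a hypothesis found on these same data. A change in total RNA per cell was not measured and stays open for every count of higher and lower genes.

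The myeloid lists fell in DOPPA. One vehicle library rich in granule transcripts does not account for the neutrophil granule list, because the smallest fall of the DOPPA mean against any single vehicle library, vehicle 1, had a median log2 ratio of -1.83 ± 0.64. For the monocyte and macrophage list the smallest such fall, against vehicle 2, was -0.38 ± 0.61. By it, an effect of DOPPA on the list as a whole and many monocyte-like cells in vehicle libraries 1 and 3 cannot be told apart. This comparison does not use the pairing by number. With the replicate block 11 of the 18 members fell (camera adjusted p = 1.6e-05). The marker mean, however, was 0.20 in vehicle 2 and 0.22 in DOPPA 2. The labels do not say that the numbers mark shared cells, so the question stays open. The members went apart: 9 of the 18 lay lower in all 3 DOPPA libraries than in vehicle 2, 4 lay higher in all 3 and 5 on both sides. Among the 9, MRC1 stood at 77.1 CPM in vehicle 2 and at most at 3.30 in DOPPA, FCN1 at 18.6 and 0.18, CD86 at 10.2 and 0.99 and CD14 at 5.58 and 0.26. The fall of these genes was thus not confined to vehicle libraries 1 and 3, but this rests on a single vehicle library and on genes chosen after their values were seen. For the MHC class II list, levels were read from a line through the vehicle libraries at the mean monocyte marker level of DOPPA. The DOPPA libraries stood at 0.20, 0.22 and 0.27, next to vehicle 2 at 0.20. The line thus reached beyond the vehicle libraries only where vehicle 2 was left out. The level to be expected exceeded the observed one, with a median log2 ratio of observed to expected of -1.58 ± 0.35 over the 17 genes. It lay between -1.79 and -1.45 with each vehicle library left out in turn. This cannot exclude fewer monocyte-like cells alone. The line rests on 3 vehicle libraries, the spread is over genes, and the marker mean joins members that went apart, such as CD14 and VCAN. The members went apart: the ratio lay between -2.44 and -0.90 for the 13 genes that fell, at -0.35, -0.40 and -0.36 for LAMP3, FCER1A and CCR7, and at 2.19 for CD1C, and none of these 4 passed the test, although LAMP3 did without vehicle library 2 (adjusted p = 0.0024). The gap at the list's median therefore does not extend to these 4. Lower expression per cell and a loss of other cells that carry these genes may both account for the gap, and neither was tested.

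The endothelial and stromal list rose in DOPPA. Stromal cells in the cultures would bring the abundant transcripts COL1A1 and FN1. Their mean in the DOPPA libraries lay below COL6A3 by a mean log2 ratio of -8.40 ± 0.56 (SD, 3 libraries). This ratio followed from the levels given above, and COL6A3 is itself a member that rose, so it adds no independent support. The levels speak only to stromal cells rich in COL1A1 and FN1, and endothelial cells were not tested. Expression of the genes that rose in the blood cells themselves may account for the list and remains a hypothesis.

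The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 4648 changed genes, 3095 of them at least 2-fold, and 1 of the 10 splits, the real one, gave as many in both counts. The highest of the others gave 0 (edgeR), with at most 636 genes at an unadjusted p under 0.05 against 6654 in the real split. Every other split mixes vehicle and DOPPA libraries within a side, so the difference between the groups enters its spread and pushes its counts down. The counts of the other splits, here and below, are therefore no baseline for chance. Of the splits, 4 part all 3 same-numbered pairs as the real one does, and the other 3 of these had 73, 261 and 93 genes at an unadjusted p under 0.05; the remaining splits part 1 pair.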
